A study of Mus musculus with 12 samples.

How the data were processed

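Prostates of 4 mouse genotypes were profiled by 3′ end sequencing. Per the labels' protocols, a Pten heterozygous male was bred with a Trap1 transgenic female, total RNA was extracted with Trizol and treated with DNase, and QuantSeq 3′ libraries were pooled and run on a NextSeq500. QuantSeq primes on the poly(A) tail and reads near the 3′ end, so a gene's count depends little on its length and a transcript with another 3′ end can be missed. Per the submitters' processing notes, RSEM 1.2.3 and DESeq2 were used on genome build mm10. Neither the role of each tool nor the aligner, the annotation release or the handling of unique molecular identifiers was stated. RSEM spreads reads that match several genes among them by estimated abundance, and its default model expects reads from along the whole transcript.

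The deposited table was taken to hold expected counts per gene (expected_counts), left unscaled. All values in it (100%) were whole numbers, and it was not stated if fractions had been rounded before deposit. It has 17152 Ensembl genes and 10 libraries, so 2 of 12 labelled samples had no column and the Pten WT groups hold 2 libraries each. Of its genes, 209 were at 0 in every library, and 0 mitochondrially encoded genes were present, so that list was not analysed here. The fits were planned for 12 libraries and were run on the 10 available. Gene positions came from GENCODE M21 (mm10 coordinates), in which 16908 of the identifiers were found. Among its gene symbols, 61 occur more than once, and rows were kept by identifier.

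Library totals ran from 409427 to 1681192 counts. Genes with enough counts (edgeR filterByExpr by group) numbered 11284. Counts were scaled with TMM and fitted with a robust quasi-likelihood model in edgeR 4.0.16 (R 4.3.3) with 1 coefficient for each of 4 groups, and the common dispersion was 0.420. There were 7 contrasts, namely the transgene effect in Pten het and in Pten WT, the Pten effect without and with the transgene, their interaction, and both effects averaged. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Replicate numbers were not used to pair libraries, since the labels do not say that they pair mice. Deviations from the group means correlated at −0.100 to 0.045 across genes in 12 pairs of libraries with a shared number and at −0.100 to 0.100 in 25 pairs without. In a group of 2 libraries these deviations mirror each other, so the ranges are partly fixed in advance and cannot decide whether numbers pair mice. A fold against a group with 0 counts was computed against a floor of 3 counts over the group.

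Gene lists, contrasts, the test, the rule for named genes and most alternatives were chosen before the data were examined. Of 38 lists, 31 had at least 5 tested members. They were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over 155 tests (31 lists in 5 contrasts), with the averaged contrasts adjusted separately. Beside it stand camera with an estimated correlation and the rotation test fry, directional and mixed. With an estimated correlation 0 lists were called in any contrast, while at the preset correlation 2, 5, 7, 8 and 3 were called in the first 5 contrasts, in the order above, and 3 and 7 in the averaged ones. Directional fry, which asks whether a list moves one way without comparing it with other genes, called 0 in the first 5 contrasts and 1 and 3 in the averaged ones, and mixed fry called 1, 2, 5, 6, 1, 2 and 14.

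The lists covered mitochondrial chaperones, the respiratory chain, glycolysis, the TCA cycle, the cell cycle, apoptosis, junctions, matrix, prostate secretion, PI3K signalling, stress responses, lipid metabolism, immediate early, interferon and cytokine genes, ribosomal proteins and markers of the cell types a prostate sample could hold. Lists with no call in the first 5 contrasts had these lowest camera adjusted p-values: mitochondrial chaperones and proteases 0.541, glycolysis 0.484, cell cycle 0.125, apoptosis promoting 0.758, apoptosis opposing 0.639, mesenchymal and invasion 0.210, matrix and fibroblast 0.383, basal epithelium 0.0641, PI3K, AKT and FOXO pathway 0.598, hypoxia 0.476, cholesterol and fatty acid synthesis 0.647, fatty acid oxidation 0.361, immediate early genes 0.0505, inflammatory cytokines 0.337, myeloid cells 0.286, endothelium 0.658, seminal vesicle 0.102, nerve and Schwann cells 0.239. The 7 lists with too few tested members were mitochondrially encoded transcripts (0), T and natural killer cells (1), erythroid cells (2), neuroendocrine (3), urothelium (3), B and plasma cells (4) and adipocytes (4).

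Named genes were those past the threshold with the largest changes, up to 12 in each direction, with a mean log2 CPM of at least 1, no overlap between the groups' libraries (for averaged contrasts, the same direction in both strata) and no predicted or clone name. Where fewer than 5 passed, the 10 genes with the smallest p were read. Trap1, Pten and up to 4 members per list with the smallest p were added.

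Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, library totals alone, TMM without the 20 most abundant genes, no filter, at least 10 counts in 6 libraries, only the groups compared, an adjusted p under 0.10, an absolute log2 change of at least 1, a block for the replicate number (replicate block), and each library left out. The filter was applied anew wherever libraries were left out, which gave 10821 to 12770 genes. After the data were seen, 5 were added, namely leaving out Pten het transgenic replicates 2 and 3, libraries matched on depth (also without Pten WT non-transgenic replicate 2), leaving out seminal vesicle genes, a loess correction for gene span and exon length, and the fits with libraries left out repeated on the 11284 genes tested in all libraries. The calls were tested on simulated data with 200 changed genes in each of 2 runs. Each gene was drawn independently, without shifts shared by the genes of a library. For a log2 change of 2, edgeR recovered 22.5% of changed genes for the transgene in Pten het, 20.9% for Pten without the transgene and 17.8% with it, and 41.5% for Pten averaged. For a log2 change of 1 these were 2.66%, 0%, 2.13% and 11.6%, and false calls were 11.1%, 13.3%, 11.6% and 6.67%. False calls in the same data were 23.1 to 27.9% for DESeq2 and 12.8 to 26.5% for limma-voom.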

Results

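Messenger RNA was counted in mouse prostates that carried 1 of 4 genotype combinations. The mice were Pten wild type (WT) or Pten heterozygous (het), and either carried a Trap1 transgene or did not. Pten encodes a lipid phosphatase that opposes PI3K signalling and acts as a tumour suppressor in the prostate. Trap1 encodes a mitochondrial chaperone of the HSP90 family. The labels name Pten het transgenic males as the experimental group and Pten het non-transgenic males as its control. Each library was made with QuantSeq, a kit that reads the 3′ end of polyadenylated transcripts, so a count stands for transcript ends and not for full transcripts.

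Of 12 labelled samples, 10 had values, namely 3 Pten het transgenic, 3 Pten het non-transgenic, 2 Pten WT transgenic and 2 Pten WT non-transgenic libraries. Replicate 3 of Pten WT non-transgenic and replicate 2 of Pten WT transgenic had no column and were not analysed here. Total counts were 923691 and 1681192 in the Pten WT non-transgenic libraries and 1161719 and 1161325 in the Pten WT transgenic libraries. They were 1123796, 1216288 and 913503 in the Pten het non-transgenic libraries and 982937, 409427 and 822554 in the Pten het transgenic libraries. A count of 1 equalled 0.595 to 2.44 CPM (counts scaled to a common library total of 1e6) depending on the library. A count of 0 allowed a level of up to 3 counts, which was 1.78 to 7.33 CPM, and such limits cover counting error only. The p-values for single genes and for shares of counts measure the spread between these prostates, which the labels list as separate replicates. Camera p-values at the preset correlation set list members against other genes, as if nearly independent. Fisher's exact tests count genes. The p-values of these 2 kinds do not stand for the spread between prostates.

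Trap1 (ENSMUSG00000005981, chromosome 16, 4039971 to 4077827, mm10) was not detectably higher in transgenic than in non-transgenic prostate. Its level was 45.3 ± 1.96 CPM in Pten het transgenic libraries (SD, n = 3) and 42.6 ± 14.95 CPM in Pten het non-transgenic libraries (SD, n = 3). The log2 fold change was 0.09 ± 0.61 (SE, adjusted p = 0.994, edgeR). In Pten WT prostate Trap1 stood at 25.0 ± 11.2 CPM with the transgene and at 26.5 ± 3.97 CPM without it (SD, n = 2 each). A transgene with another 3′ end would not be counted under this gene, and the labels do not describe the construct. Pten (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160) stood at 81.8 ± 12.8 CPM in Pten het non-transgenic libraries and at 86.1 ± 42.1 CPM in Pten het transgenic libraries (SD, n = 3 each). In Pten WT libraries it stood at 99.3 ± 11.7 CPM without the transgene and at 156 ± 3.52 CPM with it (SD, n = 2 each). Averaged over Trap1 genotypes, the Pten log2 change in Pten het prostate was −0.58 ± 0.30 (SE, adjusted p = 0.349), which did not pass the test. The labels do not describe the mutant allele, so a 3′ count need not follow the loss of the allele.

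**Figure D1:**
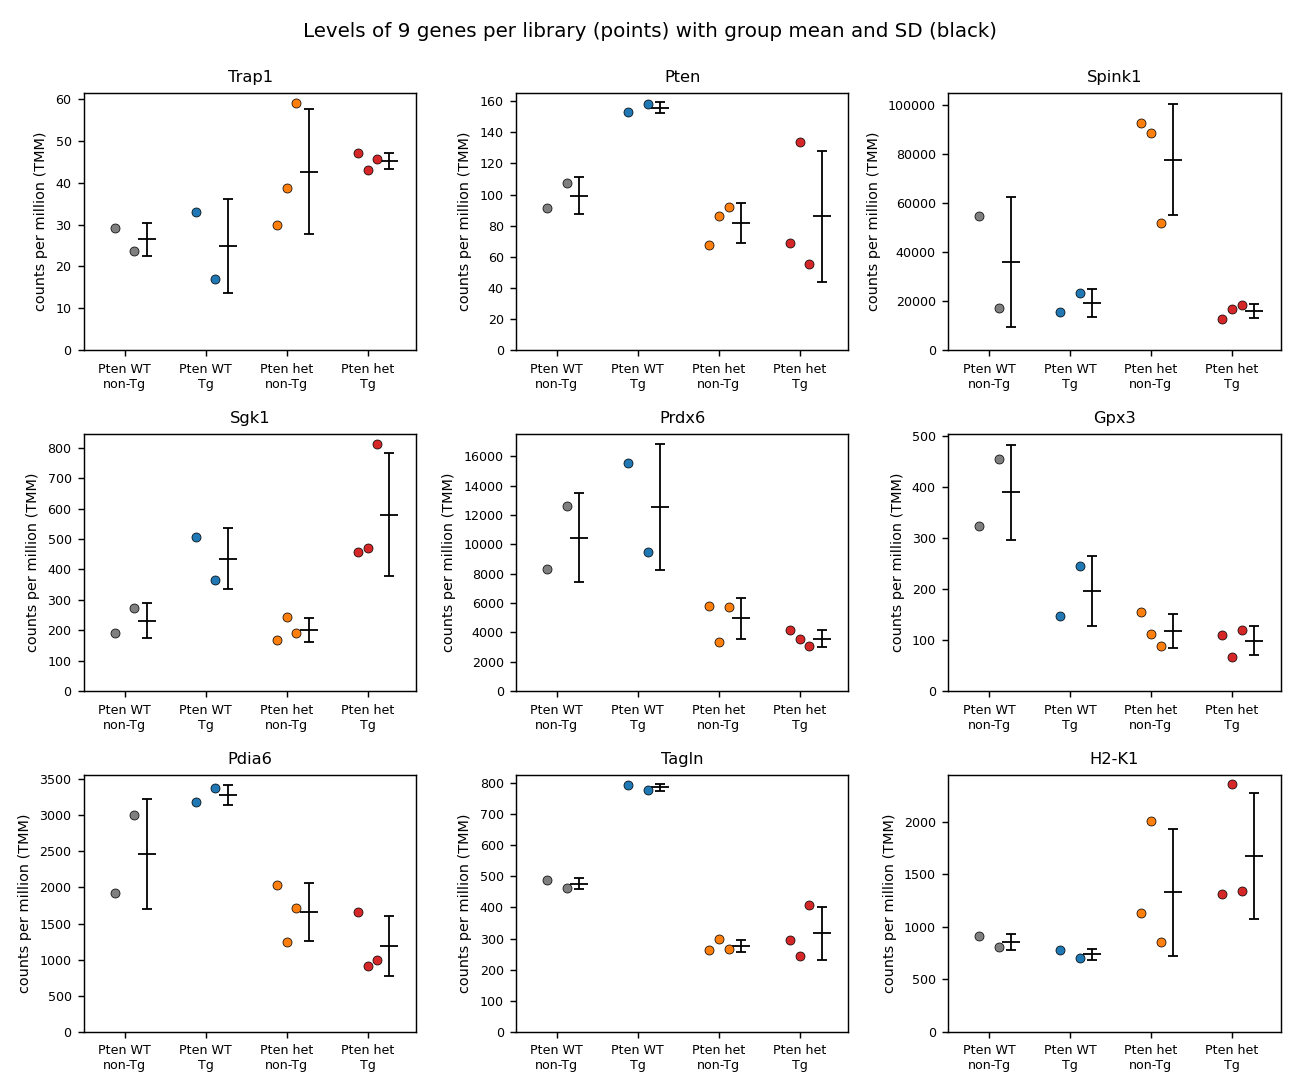
Normalised CPM of 9 genes (vertical axes) in the 10 libraries, by group (horizontal axes). Points are libraries and black marks give the group mean with its SD (n = 2 in Pten WT groups, n = 3 in Pten het groups); Sgk1 averaged 200 CPM in Pten het non-transgenic and 580 CPM in Pten het transgenic libraries.

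The first comparison asked what the Trap1 transgene changed in Pten het prostate, the contrast named by the study design. Sgk1 (chromosome 10, 21882184 to 21999903), a serum and glucocorticoid induced kinase that acts downstream of PI3K, rose 2.90-fold in transgenic prostate. It averaged 580 ± 201 CPM with the transgene and 200 ± 40.2 CPM without it (SD, n = 3 each), a log2 change of 1.53 ± 0.27 (SE, adjusted p = 0.0118). Tpm2 (chromosome 4, 43514711 to 43523765), a tropomyosin of contractile fibres, rose from 117 ± 5.51 to 284 ± 32.8 CPM, a log2 change of 1.28 ± 0.27 (SE). Npc2 (chromosome 12, 84754562 to 84773152), a lysosomal cholesterol carrier, fell from 483 ± 126 to 183 ± 21.2 CPM, a log2 change of −1.40 ± 0.26 (SE, adjusted p = 0.0118).

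In all, 9 of 11284 genes passed the test in Pten het prostate, 4 higher and 5 lower with the transgene. Hccs, the enzyme that attaches haem to cytochrome c (chromosome X, 169250193 to 169320372), had 0 counts in the Pten het non-transgenic libraries and 67 in the Pten het transgenic libraries. That was at least 32.9-fold higher against a floor of 3 counts over the group (adjusted p = 0.0290). Arglu1 (chromosome 8, 8665075 to 8690521), a coactivator linked to splicing, rose from 2244 ± 30.6 to 4600 ± 934 CPM (log2 1.03 ± 0.21). Sdf4 (log2 −1.51 ± 0.32, chromosome 4, 155992872 to 156013610) encodes a calcium-binding protein of the Golgi and fell. Sgpp1 (log2 −1.50 ± 0.29, chromosome 12, 75714249 to 75735729), a sphingosine phosphate phosphatase, and Tspan13 (log2 −1.24 ± 0.26, chromosome 12, 36014557 to 36042500), a tetraspanin, also fell. The remaining gene, 9530002B09Rik (chromosome 4, 122689275 to 122705129), lay outside the rule for named genes and was chosen after its values were seen. It fell from 8882 ± 1750 to 2984 ± 203 CPM (log2 −1.57 ± 0.21, adjusted p = 4.47e-05).

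Smooth muscle genes as a list were higher in Pten het transgenic prostate, with 12 of 13 tested members positive and a median log2 change of 0.32 (camera adjusted p = 0.000680, adjusted p = 0.762 with an estimated correlation). Of its members, 1 rose over all genes tested (Tpm2) and 4 adjusted over the list alone. The other members were Myh11 at log2 0.64 ± 0.21, Cnn1 at 0.79 ± 0.27 and Myl9 at 0.87 ± 0.34 (SE). The list's call was lost without Pten het transgenic replicate 3 (camera adjusted p = 0.0953), the library with the seminal vesicle transcripts. Prostate secretory and androgen response genes as a list were lower, with 15 of 22 tested members negative and a median of −0.33 (camera adjusted p = 2.75e-05, adjusted p = 0.227 with an estimated correlation). Of these, 0 passed over all genes tested and 1 was lower adjusted over the list alone. That member was Spink1 (chromosome 18, 43728082 to 43737557), a secreted protease inhibitor, at log2 −2.29 ± 0.44 (SE, adjusted p = 0.233 over all genes). The secreted proteins Sbp and Sbpl, whose related sequences may share reads, had log2 values of −1.55 ± 0.45 and −1.69 ± 0.59. Together the listed secretory genes took 5.78 ± 1.58% of counts in Pten het transgenic and 13.5 ± 2.10% in Pten het non-transgenic libraries (SD, n = 3 each). An exact permutation test of that share, chosen after the shares were seen, gave a two-sided p = 0.1, the smallest that 20 splits allow, and 0.2 adjusted over 8 such tests. Pten het transgenic replicate 3 stood apart from all other libraries, with 17.8% of its counts on seminal vesicle genes against 0.0780 to 0.265% elsewhere.

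The count of 9 moved with the genes tested, with single libraries and with the tool. It was 23 or 17 without Pten WT non-transgenic replicate 1 or 2 and 41 or 39 without Pten WT transgenic replicate 1 or 3, where the filter let in 12423 to 12770 genes. These counts were 11 or 10 and 5 or 5 with the same 11284 genes tested, and the count was 43 with all libraries and no filter. It was 1 or 5 without Pten het non-transgenic replicate 1 or 2, and 3 without Pten het transgenic replicate 2. DESeq2 called 43 genes and a fit with a replicate block called 4. Libraries matched on depth, which left 1 Pten het transgenic library whose spread is taken from the other groups, called 3 genes, of which 0 were among the 9, and 0 genes with the same 11284 genes tested.

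The second comparison asked what the transgene changed in Pten WT prostate, with 2 libraries in each group. Here 0 genes passed the test in edgeR, while 143 had an unadjusted p under 0.05, DESeq2 called 0 and limma-voom called 1. The 10 genes with the smallest p were read out although none passed, and all had an adjusted p of 1. They included Pet117, an assembly factor of cytochrome c oxidase, at log2 3.97 ± 1.06, and Hspa8, a constitutive cytosolic chaperone with many processed copies, at 2.81 ± 0.76. The ribosomal protein gene Rplp1 stood at 2.38 ± 0.60, the cell polarity gene Inadl at −1.80 ± 0.54 and the cytochrome P450 gene Cyp2f2 at −2.31 ± 0.67 (SE, n = 2 each). Without Pten WT non-transgenic replicate 2 the count was 2, and without Pten WT transgenic replicate 1 or 3 it was 1 or 3, against 1, 0 and 0 with the same 11284 genes tested.

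Smooth muscle genes were also higher as a list in Pten WT transgenic prostate. All 13 tested members were positive, with a median log2 change of 0.78 (camera adjusted p = 2.04e-17, adjusted p = 0.227 with an estimated correlation). None passed over all genes tested in edgeR (0) or adjusted over the list alone (0), with Myl9 at 1.11 ± 0.40, Cnn1 at 0.89 ± 0.32, Des at 1.25 ± 0.48 and Tagln at 0.72 ± 0.29. Integrated stress and ER stress genes had 22 of 26 members positive, among them Pdia4 at 0.95 ± 0.36 and Chac1 at 2.78 ± 1.15, with a median of 0.40 (camera adjusted p = 1.33e-05, adjusted p = 0.762 with an estimated correlation). Of that list 0 passed over all genes and 0 adjusted over the list alone. Cytosolic heat shock genes had 12 of 15 members positive and a median of 0.83 (camera adjusted p = 0.0268, adjusted p = 0.785 with an estimated correlation), with 0 calls over all genes and 1 adjusted over the list alone, Hspa8. Skeletal muscle genes had 5 of 6 positive and a median of 0.89 (camera adjusted p = 0.0336, adjusted p = 0.785 with an estimated correlation), with 0 calls over all genes and 0 adjusted over the list alone. Proximal or progenitor-like luminal genes had 10 of 11 negative and a median of −1.31 (camera adjusted p = 0.0110, adjusted p = 0.785 with an estimated correlation), also with 0 calls over all genes and 0 adjusted over the list alone. Of these 5 list calls, the smooth muscle call held with each library left out. Without Pten WT transgenic replicate 3 the calls of stress, heat shock and skeletal muscle genes were lost (camera adjusted p = 0.147, 0.644 and 0.390). Those of heat shock, skeletal muscle and progenitor-like genes were lost without Pten WT non-transgenic replicate 1 (0.410, 0.202 and 0.0702) and with a replicate block (0.334, 0.336 and 0.552). That of skeletal muscle genes was also lost without Pten WT non-transgenic replicate 2 (0.128) and that of progenitor-like genes without Pten WT transgenic replicate 1 (0.0745).

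The difference between both transgene effects was tested as an interaction, and 0 genes passed in edgeR. At an unadjusted p under 0.05 there were 374 genes, DESeq2 called 3 and limma-voom called 2. The smallest p-values belonged to Ankzf1, a mitochondrial stress and ribosome rescue factor, at log2 2.76 ± 0.64, Tspan13 at −1.66 ± 0.40 and Arglu1 at 1.34 ± 0.33 (SE, adjusted p = 0.416 each). As a list, prostate secretory genes had a more negative transgene effect in Pten het than in Pten WT prostate, with 14 of 22 members negative (camera adjusted p = 0.0142, adjusted p = 0.762 with an estimated correlation). So had integrated stress and ER stress genes (camera adjusted p = 0.0330, adjusted p = 0.816 with an estimated correlation) and cytosolic ribosomal protein genes (camera adjusted p = 0.0358, adjusted p = 0.785 with an estimated correlation). In these lists 0 members passed over all genes and 0 adjusted over the list alone. Without Pten WT transgenic replicate 3 the calls of secretory and stress genes were lost (camera adjusted p = 0.328 and 0.473), as they were without Pten het transgenic replicate 3 (0.0588 and 0.0762), where that of ribosomal protein genes was lost too (0.0833). Secretory genes also lost theirs without Pten het non-transgenic replicate 1 (0.0736). Stress genes lost it without Pten WT non-transgenic replicate 1 (0.168), Pten het non-transgenic replicate 3 (0.334) or Pten het transgenic replicate 2 (0.148) and with a replicate block (0.108). Ribosomal protein genes lost it without Pten WT non-transgenic replicate 2 (0.1002), Pten WT transgenic replicate 1 (0.225) or Pten het non-transgenic replicate 1 (0.0784), and with the same 11284 genes tested also without Pten het non-transgenic replicate 2 (0.0552). Without Pten WT non-transgenic replicate 1 the count was 2, and without Pten WT transgenic replicate 3 or Pten het non-transgenic replicate 2 it was 1 each, against 1, 0 and 1 with the same 11284 genes tested.

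Averaged over Pten genotypes, 2 genes changed with the transgene. Sgk1 rose by a log2 of 1.22 ± 0.21 (SE, adjusted p = 0.00892), and 9530002B09Rik fell by a log2 of 0.92 ± 0.16 (SE, adjusted p = 0.00892). Pet117 stood at 3.23 ± 0.65 (adjusted p = 0.0539) and Tpm2 at 0.92 ± 0.21 (adjusted p = 0.162), short of the threshold. Smooth muscle genes were higher as a list, with 13 of 13 members positive and a median of 0.66 (camera adjusted p = 3.80e-14, adjusted p = 0.142 with an estimated correlation). Of these 0 passed over all genes and 7 adjusted over the list alone, and a directional rotation test (fry) of the list passed (adjusted p = 0.0378). Prostate secretory genes tested lower (camera adjusted p = 8.13e-05, adjusted p = 0.142 with an estimated correlation) although 11 of 22 members were positive, with a median of −0.05 and a mean of −0.23, with 0 calls over all genes and 2 adjusted over the list alone. Integrated stress and ER stress genes tested higher, with 20 of 26 positive and a median of 0.18 (camera adjusted p = 0.00561, adjusted p = 0.715 with an estimated correlation), with 0 calls over all genes and 0 adjusted over the list alone. That call was lost without Pten WT non-transgenic replicate 1 (camera adjusted p = 0.142), Pten WT transgenic replicate 3 (0.409), Pten het non-transgenic replicate 2 (0.174) or Pten het transgenic replicate 1 (0.243), and with a replicate block (0.120). The count of 2 was 0 without Pten het non-transgenic replicate 1, 1 without Pten het transgenic replicate 2, 11 without Pten WT non-transgenic replicate 2, 6 or 18 without Pten WT transgenic replicate 1 or 3, and 5 without Pten het non-transgenic replicate 3 or Pten het transgenic replicate 3. With the same 11284 genes tested these were 0, 2, 9, 0 or 1, and 5 or 6. The count was then also 0 without Pten WT non-transgenic replicate 1, 3 without Pten het non-transgenic replicate 2 and 1 without Pten het transgenic replicate 1.

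**Figure D2:**
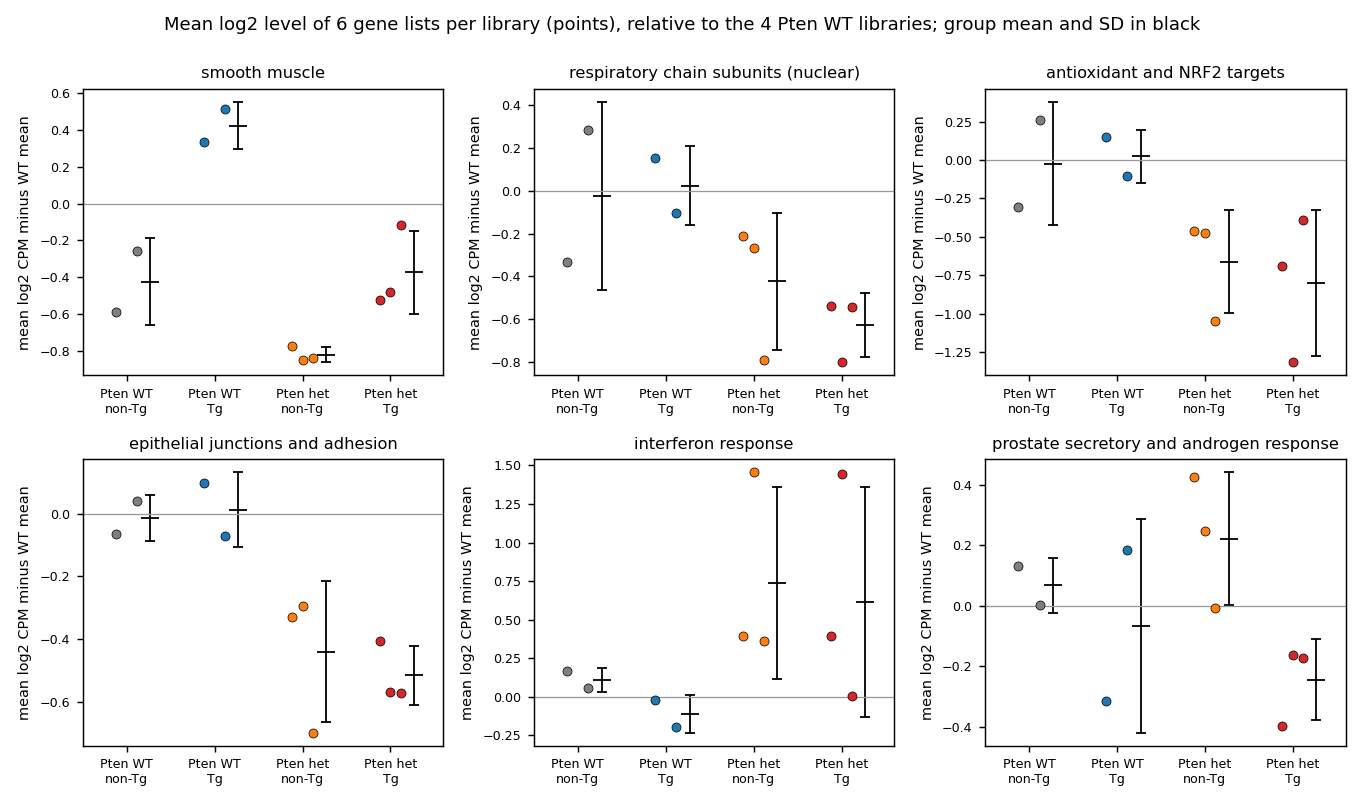
Mean log2 CPM of the tested members of 6 gene lists in each of the 10 libraries, relative to the mean of the 4 Pten WT libraries (vertical axes), by group (horizontal axes). Points are libraries and black marks give the group mean with its SD (n = 2 in Pten WT groups, n = 3 in Pten het groups); in the averaged Pten comparison the median log2 change was −0.85 for smooth muscle genes and 1.00 for interferon response genes.

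The Pten comparisons asked what the loss of 1 Pten allele changed, first without the transgene. In Trap1 non-transgenic prostate Gpx3 (chromosome 11, 54902453 to 54910377), a secreted glutathione peroxidase, fell from 389 ± 93.2 CPM in Pten WT (SD, n = 2) to 118 ± 33.4 CPM in Pten het (SD, n = 3). Its log2 change was −1.72 ± 0.35 (SE, adjusted p = 0.0430). Ppp3ca (chromosome 3, 136670124 to 136937727), the catalytic subunit of calcineurin, fell from 1330 ± 174 to 571 ± 137 CPM (log2 −1.22 ± 0.25). Rnf149 (chromosome 1, 39551296 to 39577405), a ubiquitin ligase, fell from 2015 ± 681 to 886 ± 197 CPM (log2 −1.19 ± 0.25). Yeats2 (chromosome 16, 20141063 to 20232573), a histone reader, rose by a log2 of 1.62 ± 0.33, and the small nucleolar RNA Snord87 (chromosome 1, 9942463 to 9942549) by 1.46 ± 0.30.

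In all, 7 genes passed in non-transgenic prostate, 4 higher and 3 lower in Pten het. The other 2 higher genes were outside the rule for named genes and were chosen after their values were seen. D030028A08Rik was at least 36.6-fold higher, with 134 counts in Pten het and 0 in Pten WT non-transgenic libraries, and Gm26225, a small RNA gene, had a log2 change of 2.48. Antioxidant genes as a list were lower, with 15 of 23 negative and a median of −0.50 (camera adjusted p = 0.000267, adjusted p = 0.762 with an estimated correlation), with 1 lower over all genes (Gpx3) and 2 adjusted over the list alone (Gpx3 and Prdx6). Cytosolic heat shock genes were higher, with 12 of 15 positive and a median of 0.83 (camera adjusted p = 0.000675, adjusted p = 0.762 with an estimated correlation), with 0 calls over all genes and 2 adjusted over the list alone. Respiratory chain genes had 39 of 52 negative and a median of −0.38 (camera adjusted p = 0.00158, adjusted p = 0.785 with an estimated correlation), with 0 calls over all genes and 1 adjusted over the list alone. Smooth muscle genes had 11 of 13 negative and a median of −0.49 (camera adjusted p = 0.00318, adjusted p = 0.762 with an estimated correlation), with 0 calls over all genes and 3 adjusted over the list alone. Interferon response genes had 15 of 20 positive (camera adjusted p = 0.0330, adjusted p = 0.816 with an estimated correlation), with 0 calls over all genes and 0 adjusted over the list alone. Junction genes had 20 of 28 negative (camera adjusted p = 0.0370, adjusted p = 0.762 with an estimated correlation) and TCA cycle genes 16 of 19 negative (camera adjusted p = 0.0461, adjusted p = 0.762 with an estimated correlation), each with 0 calls over all genes and 0 adjusted over the list alone.

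These list calls moved with single libraries. Without Pten WT non-transgenic replicate 2 the camera adjusted p was 0.774 for respiratory chain, 0.523 for TCA cycle, 0.143 for each of antioxidant, junction and smooth muscle, and 0.0784 for interferon response genes. The interferon call was also lost without Pten het non-transgenic replicate 2 (camera adjusted p = 0.368) or Pten WT non-transgenic replicate 1 (0.0718), and the last also ended the heat shock call (0.0707), which was kept there with the same 11284 genes tested (0.0421). TCA cycle genes lost theirs without Pten het non-transgenic replicate 2 (0.132) and with a replicate block (0.0524), and junction genes without Pten het non-transgenic replicate 3 (0.0857) and with a replicate block (0.103). With the same 11284 genes tested, junction genes also lost theirs without Pten WT non-transgenic replicate 1 (0.0679) or Pten WT transgenic replicate 3 (0.0517). TCA cycle genes did so without Pten WT transgenic replicate 1 (0.0548) or 3 (0.0553) or Pten het transgenic replicate 3 (0.0503).

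The count of 7 was 25 or 2 without Pten WT non-transgenic replicate 1 or 2 and 43 or 44 without Pten WT transgenic replicate 1 or 3. The latter are not part of this comparison, and the filter let in 12423 to 12770 genes in these 4 fits. With the same 11284 genes tested the counts were 8 or 1 and 19 or 18, and with all libraries and no filter 51. It was 2, 3 or 4 without Pten het non-transgenic replicate 1, 2 or 3, and 2 without Pten het transgenic replicate 1 or 2 (2 and 7 with the same 11284 genes tested), while DESeq2 called 77 genes and limma-voom 54. Libraries matched on depth, with 1 Pten WT non-transgenic library left, called 0 in edgeR.

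In Trap1 transgenic prostate 276 genes differed between Pten het and Pten WT, 153 higher and 123 lower. Fam193a (chromosome 5, 34369933 to 34486456) rose by a log2 of 2.32 ± 0.31 (SE, adjusted p = 2.52e-05), and Ankzf1 (chromosome 1, 75192151 to 75199387) rose to 203 ± 81.4 CPM in Pten het transgenic prostate (log2 3.12 ± 0.50, adjusted p = 0.000198). Fyb, an adaptor protein of blood cells, rose by 3.43 ± 0.87, Crabp1, a retinoic acid carrier, by 3.33 ± 0.90, and Myo9b, a myosin, by 3.16 ± 0.87. Mycbpap was at least 29.4-fold higher and Lgals7, a galectin of stratified epithelium, at least 19.0-fold higher, each against 0 counts in Pten WT transgenic libraries. Rpl26 was at least 22.6-fold higher on the same floor, but ribosomal protein genes have many processed copies that can share reads.

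Among the 123 lower genes, Prdx6 (chromosome 1, 161240112 to 161251219), a peroxiredoxin, fell by a log2 of 1.81 ± 0.25 and Pdia6 (chromosome 12, 17266545 to 17284770), a disulphide isomerase of the endoplasmic reticulum, by 1.47 ± 0.26. The GTPase regulator Chn2 (chromosome 6, 54039554 to 54301810) fell by 2.97 ± 0.43, Pecr, a peroxisomal enoyl-CoA reductase, by 4.53 ± 1.15 and Cldn4, a claudin of tight junctions, by 2.16 ± 0.46. Taf9b, Nxt2 and Gpr146 had 0 counts in Pten het transgenic libraries and were at least 31.9-fold, 27.9-fold and 16.1-fold lower. Atad1 (chromosome 19, 32671638 to 32739786), a mitochondrial outer membrane ATPase gene next to Pten, fell from 84.7 ± 23.5 CPM (SD, n = 2) to 15.5 ± 4.73 CPM (SD, n = 3), a log2 change of −2.48 ± 0.60 (adjusted p = 0.0170).

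By list, smooth muscle genes were lower in Pten het transgenic prostate, with 11 of 13 negative and a median of −1.01 (camera adjusted p = 2.00e-05, adjusted p = 0.762 with an estimated correlation). Over all genes 4 fell, among them Tagln (log2 −1.31 ± 0.26) and Actg2 (−2.23 ± 0.62), and 7 adjusted over the list alone. Respiratory chain genes had 41 of 52 negative and a median of −0.65 (camera adjusted p = 0.000155, adjusted p = 0.785 with an estimated correlation), with 2 lower over all genes and 3 adjusted over the list alone. Antioxidant genes had 16 of 23 negative and a median of −0.58 (camera adjusted p = 0.00209, adjusted p = 0.762 with an estimated correlation), with 1 lower over all genes and 3 adjusted over the list alone. Integrated stress and ER stress genes had 19 of 26 negative and a median of −0.49 (camera adjusted p = 0.0229, adjusted p = 0.785 with an estimated correlation), with 4 lower both over all genes and adjusted over the list alone. These were Pdia6, Manf, Dnajc3 and Atf5. Interferon response genes had 15 of 20 positive and a median of 1.35 (camera adjusted p = 0.0260, adjusted p = 0.794 with an estimated correlation), with 2 higher over all genes (H2-D1 and H2-K1, related genes that may share reads), and 5 higher and 1 lower adjusted over the list alone. Junction genes had 21 of 28 negative and a median of −0.52 (camera adjusted p = 0.0268, adjusted p = 0.762 with an estimated correlation), with 2 lower over all genes and 3 adjusted over the list alone. Luminal genes had 9 of 11 negative (camera adjusted p = 0.0368, adjusted p = 0.785 with an estimated correlation), with 0 calls over all genes and 1 lower adjusted over the list alone. Progenitor-like luminal genes tested higher, with 8 of 11 positive and a median of 2.11 (camera adjusted p = 0.0443, adjusted p = 0.785 with an estimated correlation). Their only call over all genes was lower, the claudin Cldn4, and adjusted over the list alone 2 were higher and 1 lower. The calls of smooth muscle, respiratory chain and antioxidant genes held with each library left out. Without Pten WT transgenic replicate 3 those of stress and interferon genes were lost (camera adjusted p = 0.390 and 0.139), and without Pten het transgenic replicate 2 those of stress, interferon and progenitor-like genes (0.0775, 0.164 and 0.111). With a replicate block the interferon call was lost (0.0524). Junction and luminal genes lost theirs without Pten WT transgenic replicate 1 (0.129 and 0.195) or Pten het transgenic replicate 3 (0.0839 and 0.206). With the same 11284 genes tested, progenitor-like genes also lost theirs without Pten WT transgenic replicate 1 (0.166) or 3 (0.0522) or Pten het transgenic replicate 3 (0.0578). Stress genes did so without Pten het transgenic replicate 3 (0.0503) and luminal genes without Pten het transgenic replicate 1 (0.0501).

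Of the 276 genes, 265 had the same direction in non-transgenic prostate (96.0%, against 61.8% of all genes tested), with a median change of 0.70 there and 1.44 in transgenic prostate on the log2 scale. These genes were picked for their change in transgenic prostate, which by itself favours a larger median there. The 7 genes called in non-transgenic prostate had a median of 1.62 there and 1.89 in transgenic prostate. The interaction test above is also the test of whether the Pten effect differed between Trap1 genotypes, and it found 0 genes in edgeR, 374 at an unadjusted p under 0.05, 3 in DESeq2 and 2 in limma-voom. The Pten het transgenic libraries include replicate 3 with the seminal vesicle transcripts and replicate 2 with the lowest total. Without Pten WT transgenic replicate 1 the count of 276 was 56, and without Pten WT transgenic replicate 3 it was 214. Without Pten het transgenic replicate 2 it was 142, and libraries matched on depth, with 1 Pten het transgenic library left, gave 48. With the same 11284 genes tested these were 30, 122, 146 and 18. After a correction for gene length 168 genes were called, 119 higher and 49 lower. That correction also moved the median change of all genes from −0.017 to 0.131, which by itself favours higher over lower calls.

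Averaged over Trap1 genotypes, 410 genes differed between the 6 Pten het and the 4 Pten WT libraries, 208 higher and 202 lower in Pten het. Prdx6 fell in Pten het prostate by a log2 of 1.45 ± 0.18 (SE, adjusted p = 3.80e-06). Chn2 fell by 2.54 ± 0.30 and Cd59a (chromosome 2, 104095801 to 104115354), a membrane inhibitor of complement, by 2.17 ± 0.37. Fyb (chromosome 15, 6522853 to 6663313) rose by 3.97 ± 0.67, Crabp1 by 2.95 ± 0.60, Naip6, an inflammasome receptor, by 4.37 ± 0.94 and Pttg1, the securin of cell division, by 3.84 ± 0.95. Lower genes included the lipase gene Pnpla2 (−1.41 ± 0.35), the ribonuclease gene Ang (−2.55 ± 0.74), the lipoxygenase gene Alox12 (−2.11 ± 0.51) and the neighbour of Pten, Atad1 (−1.76 ± 0.41, adjusted p = 0.00717).

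Antioxidant genes were lower, with 16 of 23 negative and a median of −0.53 (camera adjusted p = 6.65e-05, adjusted p = 0.388 with an estimated correlation, fry adjusted p = 0.0398). Prdx6, Gpx3 (−1.35 ± 0.25) and Gpx1 (−0.88 ± 0.26) fell over all genes, which made 3, and 9 fell adjusted over the list alone. Subunits of the respiratory chain were lower, with 41 of 52 negative and a median of −0.54 (camera adjusted p = 1.67e-05, adjusted p = 0.715 with an estimated correlation). Over all genes 5 fell, among them the ATP synthase genes Atp5o (−1.61 ± 0.36) and Atp5e (−1.52 ± 0.34), the complex I gene Ndufs6 (−0.95 ± 0.22) and the cytochrome c oxidase gene Cox4i1 (−0.89 ± 0.22), and 7 adjusted over the list alone. Smooth muscle genes were lower, with 11 of 13 negative and a median of −0.85 (camera adjusted p = 1.67e-05, adjusted p = 0.388 with an estimated correlation, fry adjusted p = 0.0378). Cnn1 (chromosome 9, 22099216 to 22109630, −1.16 ± 0.21), Tagln (chromosome 9, 45929619 to 45936058, −1.05 ± 0.19), Tpm2 (−0.94 ± 0.20) and Mylk (−0.85 ± 0.20) were among 5 that fell over all genes and 7 adjusted over the list alone. Tagln averaged 276 ± 19.1 and 316 ± 83.9 CPM in Pten het (SD, n = 3 each) against 476 ± 17.8 and 787 ± 11.04 CPM in Pten WT (SD, n = 2 each), without and with the transgene. Junction genes were lower, with 21 of 28 negative and a median of −0.45 (camera adjusted p = 0.00561, adjusted p = 0.388 with an estimated correlation, fry adjusted p = 0.0378). Cldn4 (−1.45 ± 0.32), the laminin gene Lama3 (−1.86 ± 0.42) and Epcam (−0.77 ± 0.20) made 3 over all genes, and 5 fell adjusted over the list alone. Luminal genes were lower, with 8 of 11 negative and a median of −0.43 (camera adjusted p = 0.0171, adjusted p = 0.715 with an estimated correlation), with Nkx3-1, a prostate homeobox gene, as the 1 call over all genes (−0.80 ± 0.21) and 2 adjusted over the list alone. That list call was lost without Pten het transgenic replicate 3 (camera adjusted p = 0.0865) and, with the same 11284 genes tested, without Pten WT non-transgenic replicate 2 (0.0523).

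Interferon response genes were higher in Pten het prostate, with 16 of 20 positive and a median of 1.00 (camera adjusted p = 0.00561, adjusted p = 0.715 with an estimated correlation). The antiviral genes Rsad2 (chromosome 12, 26442746 to 26456452, 3.10 ± 0.81) and Ifit1 (3.62 ± 1.06), the signal transducer Stat2 (1.19 ± 0.33) and the class I antigen genes H2-D1 (1.10 ± 0.27) and H2-K1 (0.90 ± 0.22) made 5 over all genes, and 6 rose adjusted over the list alone. The list call held with each library left out, but the libraries stood apart. The mean log2 level of the list relative to Pten WT was 1.45 in Pten het non-transgenic replicate 2 and 1.44 in Pten het transgenic replicate 2, 0.36 to 0.39 in 3 Pten het libraries and 0.0015 in Pten het transgenic replicate 3, against −0.20 to 0.17 in the Pten WT libraries. Cytosolic heat shock genes were higher, with 12 of 15 positive and a median of 0.63 (camera adjusted p = 0.00875, adjusted p = 0.715 with an estimated correlation), with Hsp90ab1 as the 1 call over all genes (0.62 ± 0.17) and 3 adjusted over the list alone. The list call was lost without Pten WT non-transgenic replicate 1 (camera adjusted p = 0.122) or Pten het transgenic replicate 1 (0.0873). Prostate secretory genes went both ways and were not called as a list (camera adjusted p = 0.729). Azgp1 (chromosome 5, 137981520 to 137990233), a secreted glycoprotein, rose by 1.45 ± 0.24 (1 over all genes), while Cst3 (−1.14 ± 0.23), Tgm4 (−0.77 ± 0.17), Pbsn (−0.98 ± 0.22) and Nkx3-1 fell (4 over all genes), with the same 1 higher and 4 lower adjusted over the list alone. Integrated stress and ER stress genes were not called as a list (camera adjusted p = 0.145), with Pdia6 (−1.01 ± 0.18), Atf5 (−0.85 ± 0.24) and Dnajc3 (−0.63 ± 0.18) as 3 lower over all genes, and 1 higher and 4 lower adjusted over the list alone. PI3K, AKT and FOXO pathway genes were not called either (camera adjusted p = 0.729), with Klf9 lower (−0.96 ± 0.24), Sesn1 higher (2.12 ± 0.62), and 1 higher and 3 lower adjusted over the list alone. Myeloid genes had 11 of 12 positive and a median of 1.37 but passed neither as a list (camera adjusted p = 0.145) nor by gene (0 in edgeR).

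Shares of counts were also compared between Pten genotypes. Small nucleolar, small nuclear and Cajal body RNA genes took 2.18 ± 0.303% of counts in the 6 Pten het libraries and 1.21 ± 0.192% in the 4 Pten WT libraries (SD), without overlap (1.83 to 2.57% against 1.04 to 1.48%). An exact permutation test over 210 splits gave a two-sided p = 0.00476, or 0.0190 adjusted over 8 such tests. These tests were chosen after the shares were seen. The kit primes on poly(A) tails, so counts under these genes need not stand for the mature small RNAs. The source of these counts was not tested. The nuclear RNAs Malat1 and Neat1 together took 6.28 ± 0.965% against 4.74 ± 0.960% (SD, exact permutation p = 0.0429, adjusted p = 0.114), which did not pass, and their ranges overlapped (5.21 to 7.76% against 3.63 to 5.77%). Cytosolic ribosomal protein genes took 0.224 ± 0.0361% against 0.300 ± 0.0574% (SD, exact permutation p = 0.00476, adjusted p = 0.0190). These genes have many processed copies, and how reads that match several genes were handled upstream was not stated, so this low share need not measure their transcripts.

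The count of 410 was 179 without Pten WT non-transgenic replicate 2, 234 without Pten WT transgenic replicate 1 and 78 in libraries matched on depth, or 131, 175 and 29 with the same 11284 genes tested. After a correction for gene length it was 306, with 213 genes higher and 93 lower, and 169 of the 208 higher and 88 of the 202 lower genes were still called. The correction also moved the median change of all genes from −0.026 to 0.090, which by itself favours higher over lower calls. In counts simulated from these libraries, edgeR recovered 41.5% of genes changed by a log2 of 2 and 11.6% of genes changed by a log2 of 1 in this comparison, with 6.67% false calls. Each gene was drawn independently there, without shifts shared by the genes of a library. The share of false calls (7 of 105 calls) thus sets no bound for the 410 genes.

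**Figure D3:**
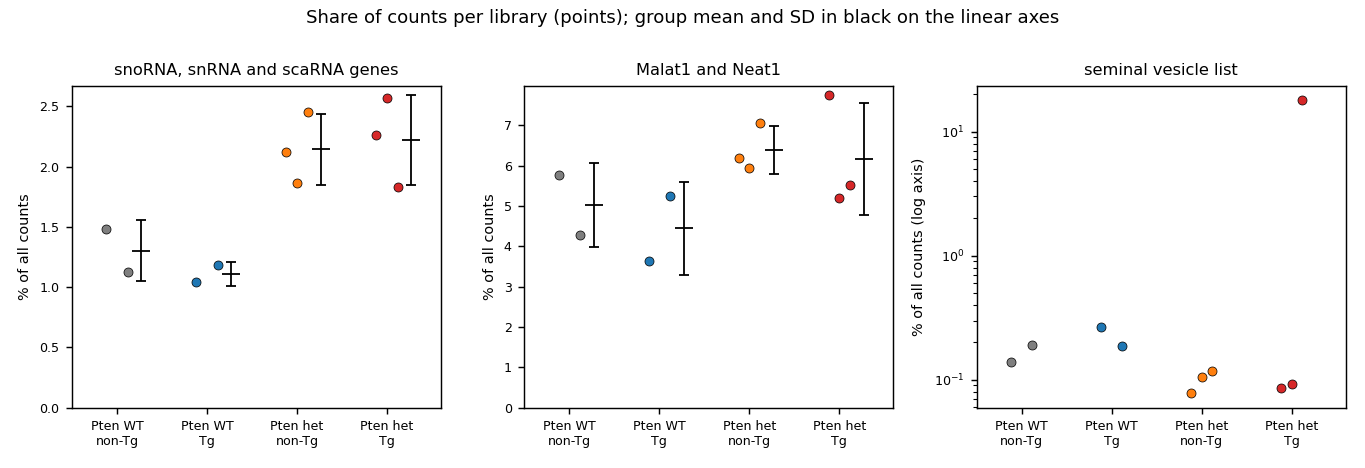
Percent of counts per library (vertical axes, logarithmic for seminal vesicle genes) on small nuclear and nucleolar RNA genes, on Malat1 and Neat1, and on seminal vesicle genes, by group (horizontal axes). Points are the 10 libraries and black marks, on the linear axes, the group mean with its SD (n = 2 or 3). Small nuclear and nucleolar RNA genes took 1.83 to 2.57% of counts in Pten het and 1.04 to 1.48% in Pten WT libraries. Of the libraries, 1 Pten het transgenic library held 17.8% seminal vesicle counts.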

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

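The tests of the luminal share, of gene length by direction and of the source of the seminal vesicle transcripts were chosen after the results were seen, and matching on depth and the gene length correction were added after the data were seen.

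The difference between both transgene effects was past the threshold for 3 gene lists at a preset correlation, while edgeR called 0 genes (374 at an unadjusted p under 0.05), DESeq2 3 and limma-voom 2. Prostate secretory genes differed with an adjusted p = 0.0142 (14 of 22 members negative, median log2 difference −0.40), integrated stress and ER stress genes with 0.0330 (20 of 26 negative, −0.44) and cytosolic ribosomal protein genes with 0.0358 (20 of 24 negative, −0.58). With an estimated correlation the adjusted p-values were 0.762, 0.816 and 0.785, so these 3 differences rest on the preset correlation. Each was also lost with any of several single libraries left out, with adjusted p-values of up to 0.328 for secretory, 0.473 for stress (both without Pten WT transgenic replicate 3) and 0.225 for ribosomal protein genes (without Pten WT transgenic replicate 1).

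For 410 genes the levels differed between Pten het and Pten WT prostate. The groups also differed in depth and in the share of counts on small nuclear and nucleolar RNA genes. Of 100 splits within Trap1 genotypes, 1, the real one, gave as many calls, and the highest other split gave 85. Chance is thus unlikely but not excluded, and such splits cannot speak on other differences that follow genotype. Depth stays open, because the 410 genes were called in libraries that include the 7 matched on depth, which favours a kept change. In those 7 the median change was 0.942 against 1.07 in all, with 410 of 410 in the same direction. The tables argue against the seminal vesicle library as the cause (median 1.09 without it, 376 called). They also argue against gene length as the whole cause (257 of 410 still called and 406 in the same direction after correction, median 0.958 against 1.07). Smooth muscle markers fell (median −0.85, mean −0.58 ± 0.179 SEM over markers), against a lower luminal share as the only change of cell types. Myeloid markers, not called as a list, went the other way (mean 1.30 ± 0.378 SEM over markers). These SEM treat markers as replicates and do not measure the spread between prostates. For smooth muscle genes the directional fry test above, which does, passed. Medians of other markers were −0.06 for fibroblasts, 0.68 for endothelium (0.21 with groups at 0 set to the floor), −0.56 for nerve, 0.11 for basal and 0.71 for progenitor-like luminal cells. A lower luminal share beside other changes stays open, since luminal markers were lower too (8 of 11, median −0.43). By direction 169 of the 208 higher genes and 88 of the 202 lower genes were still called. For the lower genes the median moved from −1.07 to −0.87, with a median SE of 0.249 and 0.252. The correction also moved the median change of all genes from −0.026 to 0.090. Such a shift by itself favours higher over lower genes, so the difference between directions need not reflect gene length. A part played by gene length stays open for the lower genes. A larger share of nuclear RNA stays open and may contribute, because 94 nuclear RNA genes outside the 410 had a median change of 1.11 (0.992 with 22 genes at their floor), and their score followed that of the 410 genes within groups with r = 0.593 (Spearman rho 0.624, exact permutation p = 0.118 over 144 permutations, r = 0.543 without the 2 farthest libraries). The loss of 1 Pten allele is the difference the design names and stays open beside depth, cell makeup and nuclear RNA share. Nuclear RNA share and Pten genotype cannot be told apart in these 10 libraries.

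The 9 genes that changed with the transgene in Pten het prostate are a small set from 3 libraries against 3. Of 10 splits, 1, the real one, gave as many as 9 calls and the highest other gave 1, and 10 splits are too few for a share under 0.05. The 9 genes were called with these libraries included, which favours a kept change when 1 is left out. The changes did not rest on the seminal vesicle library alone (median change 1.52 without it against 1.498 with it, 6 called). Without the shallowest library, Pten het transgenic replicate 2, the median was 1.38 with 2 called, and the median SE went from 0.267 to 0.287. A part played by that library stays open. The score of the 410 genes (mean of higher minus lower) was 2.69, 3.18 and 2.71 in Pten het transgenic and 1.82, 2.13 and 2.24 in Pten het non-transgenic libraries. Small nuclear and nucleolar RNA genes took 2.22 ± 0.372% and 2.14 ± 0.294% of counts (SD, exact permutation p = 0.8, chosen after the shares were seen). Whether the 9 genes follow that score was not tested, so this stays open too. An effect of the transgene stays open as a hypothesis, since Trap1 counts did not show the transgene. For the 2 genes changed on average over Pten genotypes, 9 of 60 splits gave as many calls and the highest other gave 15, so chance is not excluded.

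Pten het transgenic replicate 3 held seminal vesicle transcripts far above all other libraries. Svs2 had 92500 counts there, Pate4 26128, Svs5 24633 and Svs4 1743, which were 685-fold, 215-fold, 299-fold and 13.1-fold above the highest other library in CPM. The tables argue against seminal vesicle tissue with its full set of transcripts, because 5 of 13 listed genes were over 10-fold higher, while Svs1, Svs3a and Sva had 0 counts and Svs6 had 30, against 35, 44, 21 and 133 in Pten het non-transgenic replicate 2, where Svs2 had only 157. They also argue against the transgene, since the higher of the other Pten het transgenic libraries held 0.0926% against up to 0.118% in Pten het non-transgenic libraries. Tissue or RNA of another makeup stays open and was not tested.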

How the results depend on the processing

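Of the alternatives below, the removal of both Pten het transgenic replicates 2 and 3, matching on depth, leaving out seminal vesicle genes, the gene length correction and the repeats with the same 11284 genes tested were chosen after the data were seen.

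The transgene count in Pten het prostate (9) was 43 with DESeq2, 43 without a filter, 4 with a replicate block, 1 without Pten het transgenic replicates 2 and 3, 3 in libraries matched on depth, and 1 to 41 with each library left out. In Pten WT prostate (0) it was 1 with limma-voom, 1 without a filter and 0 to 3 with each library left out. The interaction count (0) was 3 with DESeq2, 2 with limma-voom, 3 without a filter, 1 without Pten het transgenic replicates 2 and 3, and 0 to 2 with each library left out. The averaged transgene count (2) was 10 with DESeq2, 4 with limma-voom, 12 without a filter, 0 with at least 10 counts in 6 libraries, 1 at an absolute log2 change of at least 1, 0 without Pten het transgenic replicates 2 and 3, 4 when matched on depth, 1 with the gene length correction, and 0 to 18 with each library left out.

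The Pten count without the transgene (7) was 77 with DESeq2, 54 with limma-voom, 3 with DESeq2 size factors, 3 with library totals alone, 51 without a filter, 2 with at least 10 counts in 6 libraries, 24 at an adjusted p under 0.10, 28 without Pten het transgenic replicates 2 and 3, 0 when matched on depth, 11 without seminal vesicle genes, 2 with the gene length correction, and 2 to 44 with each library left out. With the transgene (276) it was 436 with DESeq2, 111 without Pten het transgenic replicates 2 and 3, 48 when matched on depth, 168 with the gene length correction, and 56 to 347 with each library left out. The averaged Pten count (410) was 618 at an adjusted p under 0.10, 248 at an absolute log2 change of at least 1, 78 when matched on depth, and 179 to 489 with each library left out, while the replicate block gave 427. With the gene length correction it was 306, with 213 higher and 93 lower against 208 and 202. A stricter or looser threshold changes counts by construction, and the cause of most other differences was not tested. Leaving out a Pten WT library also let 12423 to 12770 genes through the filter. With the same 11284 genes tested, the counts with each library left out ran from 1 to 12 for the transgene in Pten het (9), 0 to 1 in Pten WT (0), 0 to 1 for the interaction (0) and 0 to 9 averaged (2). They ran from 1 to 19 for Pten without the transgene (7), 30 to 342 with it (276) and 131 to 497 averaged (410), so the rise to 41 and most of that to 44 came with the added genes. Among these were 122 and 146 (of 276) without Pten WT transgenic replicate 3 and Pten het transgenic replicate 2, and 175 (of 410) without Pten WT transgenic replicate 1. Without Pten het transgenic replicates 2 and 3 they were 0, 0, 0, 0, 5, 33 and 287 in the same order, and when matched on depth 0, 0, 0, 2, 0, 18 and 29. Where an alternative leaves 1 library in a group (matching on depth, both Pten het transgenic replicates removed, or 1 Pten WT library removed), that library is assumed to vary like the other groups.

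No called named gene or called list changed direction under the alternatives run for it. Of 124 calls of named genes, a gene counted once per contrast, 103 stayed with a replicate block, 91 with limma-voom, 72 with the gene length correction and 19 when matched on depth. All 25 list calls of the first 5 contrasts, a list counted once per contrast, were lost with an estimated correlation, and 18 were kept with a replicate block. With each library left out, 41 of 250 such list results lost the call, and 7 of 100 did for the averaged contrasts (51 and 8 with the same genes tested, 40 and 7 of them in both). Of the 10 list calls in the averaged contrasts, 9 were kept with a replicate block and 0 with an estimated correlation. For the Pten log2 change with the transgene in Pten het prostate, which did not pass, the sign turned with limma-voom (−0.13), the replicate block (−0.0035), without Pten het transgenic replicates 2 and 3 (−0.26), when matched on depth (−0.26), with the gene length correction (−0.019) and with single libraries left out (−0.41 to 0.27). For Trap1 it ranged from −0.12 to 0.37 in Pten het and from −0.64 to 0.30 in Pten WT prostate with each library left out. The cause was not tested. In the Pten comparisons limma-voom moved the median of all genes to −0.13 to −0.17, the replicate block to −0.07 to −0.14, and the gene length correction to 0.07 to 0.13, so changes near those sizes are relative to them. Data were also simulated with the depth and the spread per gene of these libraries, each gene drawn independently. A log2 change of 1 was then recovered for at most 11.6% of changed genes by edgeR and 16.9% by DESeq2 (with 6.67% and 24.5% false calls). How much of that is due to depth was not tested.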

Other observations

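All tests in this part were chosen after the results were seen.

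Genes of RNA processing stood out among those higher in Pten het prostate. Rbm39 rose by a log2 of 1.37 ± 0.18, Rbm25 by 1.27 ± 0.17, Srek1 by 1.23 ± 0.18 and Luc7l3 by 1.23 ± 0.18 (SE, 6 Pten het against 4 Pten WT libraries), splicing factors or their partners that lay outside the rule for named genes. Description words for splicing, RNA binding, small nuclear ribonucleoproteins, polyadenylation, DEAD box proteins or RNA polymerase II or III picked 211 tested genes. The set is thus wider than splicing, and its higher genes include Brf1 and Ddx17. Of the 211, 16 were among the 208 higher genes against 3.89 by chance (odds ratio 4.65, two-sided Fisher's exact p = 1.74e-06). Another 4 were among the lower genes, and the median log2 change over all 211 was 0.17, so most of the set did not move with the examples. Small nucleolar, small nuclear and Cajal body RNA genes gave 13 of 102 against 1.88 by chance (odds ratio 8.23, two-sided Fisher's exact p = 4.31e-08), with 0 among the lower genes and a median of 1.38 over all 102, and 3 of the 13 were still called after a correction for gene length, with 13 in the same direction and their median going from 1.68 to 1.00 (median SE 0.334 and 0.326). Of the 16 RNA processing genes 16 were still called. Among the 13 were Snord87 at 1.68 ± 0.22 and Snora23 at 1.03 ± 0.22. Several of these products stay in the nucleus, and the share of counts on small nuclear and nucleolar RNA genes was higher in the same libraries.

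Genes described by words for the secretory pathway or for membrane proteins stood out among those lower in Pten het prostate. Pdia3, a disulphide isomerase, fell by a log2 of 1.23 ± 0.18, the cargo receptor Tmed10 by 1.18 ± 0.20, the signal peptidase subunit Spcs2 by 1.12 ± 0.22 and the KDEL receptor Kdelr1 by 0.89 ± 0.20 (SE). Description words for the endoplasmic reticulum, the Golgi, vesicles, lysosomes, signal peptides, glycosyltransferases, tetraspanins or transmembrane proteins, among others, picked 440 tested genes. Of these, 31 were among the 202 lower genes against 7.88 by chance (odds ratio 4.73, two-sided Fisher's exact p = 4.93e-11). Another 2 were among the higher genes, and the median was −0.33 over all 440. The set is wider than the secretory pathway, since it also holds the membrane proteins Itm2c, Tspan13 and Sema4a and the genes Atp6v1a, Atp6v0e2 and Lamtor2. After a correction for gene length 14 of the 31 were still called, but 31 kept their direction and their median went only from −1.05 to −0.82 (median SE 0.242 after it). The correction also moved the median change of all genes from −0.026 to 0.090, which by itself weakens lower calls. The share of counts on small nuclear and nucleolar RNA genes was higher in the same Pten het libraries. Adjusted over these 3 Fisher's exact tests the p-values were 1.74e-06 for RNA processing, 6.47e-08 for small nuclear and nucleolar RNA and 1.48e-10 for the secretory and membrane set. The 3 sets were chosen after the called genes were seen and were tested on those same genes. The tests also count genes and not prostates. Their p-values thus describe the called genes and are no independent support.

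Atad1, which lies 17710 bases from Pten, fell in Pten het prostate while Pten itself did not pass the test. A candidate explanation is that genes linked to the Pten locus changed together, through the strain background of the mutant allele or the allele itself. Genes other than Atad1 within 1 to 20 Mb of Pten were tested in 6 windows for calls between Pten genotypes, and the lowest adjusted p was 0.320 (two-sided Fisher's exact test, odds ratio 3.56 within 2 Mb, 2 of 17 genes, and 0 of 7 within 1 Mb). With Atad1 kept in, which repeats the observation in part, it was 0.138. This neither excludes nor bears out the hypothesis.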
